A study of Mus musculus with 15 samples.

How the data were processed

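RNA from mouse biliary organoids was measured on 15 arrays, 3 in each of 5 groups (C, HK, HN, HKN and HPN), which the sample titles give. Per the labels' protocols, organoids were kept in a serum-free medium with EGF, Rspondin-1, Wnt3a, Noggin, FGF10 and Y-27632 before extraction. Total RNA was extracted with a silica column kit, amplified with the GeneChip whole-transcript chemistry and labelled with biotin, per the labels. The deposited table holds 1 log2 value per probe set and array, summarised and normalized by the authors with a method that the sources used here do not give. The log base was read as 2 from the range of the values, 2.19 to 19.02, and no array was rescaled before the tests.

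Of 22206 probe sets, 19572 had 1 gene symbol and 2634 had none here, for 19505 symbols, 55 of them with more than 1 probe set. All 19572 Entrez identifiers matched the reference table for GRCm38.p6, and 0 symbols changed. Probe sets in the lowest 25% by mean over all arrays (under 4.14) were left out, and the probe set with the highest mean stood for its gene, which left 14627 genes. Kras, Pten and Hnf1b had no named probe set. Signal near the dim limit and 3 arrays per group limit the precision.

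All arrays entered 1 fit in limma 3.58.1 (lmFit and eBayes, R 4.3.3) with a mean per group, 10 residual and 3.98 prior degrees of freedom and no covariate or block. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p threshold of 0.05 over all genes tested. There were 8 pairwise comparisons, the interaction (HKN minus HN, less HK minus C) and an intersection-union test for HKN apart from C, HK and HN, which takes the largest of the 3 p-values where the 3 differences share a sign. Comparisons with C share the same C arrays.

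In all, 31 gene lists were fixed from general knowledge. They included Notch targets, ERK output, EGFR ligands, FoxO, glycolysis and hypoxia, cholesterol and fatty acid synthesis, ribosome biogenesis, autophagy and lysosome, cell cycle, p53, Wnt and stem cell, YAP, NF-kB, interferon, NRF2, unfolded protein response, epithelial-mesenchymal transition and matrix proteases. Lists for cell identity were biliary, hepatocyte, gastric, intestinal, pancreatic, squamous, fibroblast, immune, endothelial, tuft and motile cilia, and a sex-linked list was described without a test. Of 585 list genes, 525 had a named probe set and 453 were tested. The 30 other lists were tested in 9 contrasts with camera (preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast), 270 tests in all with 82 calls. Camera with an estimated correlation kept 3 of the calls. A relative median is a list's median less the median of all genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

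Genes were named by rule. Against C, these were the 10 largest increases and 10 largest decreases past the threshold whose arrays did not overlap between groups, which holds for 10% of genes by chance with 3 against 3. Elsewhere they were the 6 largest each way, without the overlap condition for the interaction. For lists, up to 4 members with the largest change past the threshold were named, or 2 where none passed. Targeted genes were always named, and predicted genes were passed over.

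The steps were tested on simulated data of the same size. With 100 genes changed per size, 44% were recovered at a log2 change of 1 and 91% at 2, with 6 false among 149 calls, and the shifted list was called with 0 others. The simulated genes varied independently of each other, so this says nothing about false list calls where genes vary together. Alternatives were quantile normalization, median centring, no filter or a 50% filter on dim probe sets, the mean of probe sets, eBayes with trend and robust options, array weights, only the groups compared, a replicate block, each replicate left out in turn, an estimated correlation and fry. Added after the data were seen were the Y-linked level as a covariate, the fit without HPN arrays and centring on the 75th percentile.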

Results

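Gene expression was measured with whole-transcript arrays in organoids grown from the biliary tract of mice, with 15 arrays in 5 groups of 3. All groups carried Hnf1b-CreERT2, a Cre recombinase under the control of a biliary transcription factor gene that tamoxifen switches on. C had the driver alone, HK added a Kras allele that Cre turns into the active G12D form, and HN added the active intracellular part of Notch. HKN had both Kras and Notch activated, and HPN combined active Notch with floxed alleles of Pten, the phosphatase that opposes PI3K and Akt. The series design names HKN as the group with both pathways switched on and C, HK and HN as its controls. All values are on a scale read as log2 from their range of 2.19 to 19.02, and array medians lay between 5.89 and 6.02. The labels do not say whether replicates come from separate animals or separate cultures, so p-values measure only the spread between samples.

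Notch1 was the targeted gene with a named probe set. Its level was 4.96, 5.14 and 5.03 in the C arrays, 5.70, 5.72 and 6.41 in HK, 5.64, 5.71 and 5.05 in HN, 5.35, 5.66 and 5.40 in HKN, and 4.83, 5.29 and 5.11 in HPN. The position of this probe set within the transcript was not given, so it checks nothing about the inserted Notch fragment or the labels. The highest mean was in HK, at 5.94 ± 0.40 against 5.05 ± 0.09 in C (SD, n = 3), a log2 change of 0.89 (limma, Benjamini-Hochberg adjusted p = 0.0475). That call ended without any 1 of the 6 arrays compared (adjusted p from 0.0577 without HK replicate 4 to 0.159 without HK replicate 6) and with quantile normalization (adjusted p = 0.0684). The changes were 0.42 in HN (limma, Benjamini-Hochberg adjusted p = 0.195), 0.42 in HKN (0.19) and 0.03 in HPN (0.92). Kras, Pten and Hnf1b had no named probe set and were not analysed here.

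Nrarp and Hes1, 2 of the 14 genes in the list of Notch targets, were higher in the 3 groups with active Notch. Nrarp, a feedback inhibitor that Notch switches on, stood at 9.95 ± 0.15 in C and 9.40 ± 0.36 in HK against 15.60 ± 0.17 in HN, 15.05 ± 0.36 in HKN and 14.69 ± 0.06 in HPN (SD, n = 3). Hes1, a repressor that Notch induces, stood at 9.0 ± 0.42 in C and 8.65 ± 0.50 in HK against 11.96 ± 0.33, 11.27 ± 0.69 and 11.18 ± 0.17 in HN, HKN and HPN (SD, n = 3). Against C, Nrarp was higher by 5.65 in HN, 5.10 in HKN and 4.74 in HPN (limma, Benjamini-Hochberg adjusted p = 1.02e-09, 4.22e-09 and 9.24e-09). The list did not all follow them: it passed in HN against C but not in HKN (camera, Benjamini-Hochberg adjusted p = 0.26) or HPN (0.817), and its member Lfng fell by 2.08 in HN, 3.09 in HKN and 3.23 in HPN. The first principal component, with 41.8% of the variance, set the C and HK arrays apart from the 9 arrays with active Notch. The second, with 19.1%, set HPN apart from HN and HKN. The mean level of the Y-linked genes Eif2s3y, Kdm5d and Uty was above 6 in all C and HK arrays but in 1 of 3 arrays each of HN, HKN and HPN, so this level moved with Notch status.

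**Figure D1:**
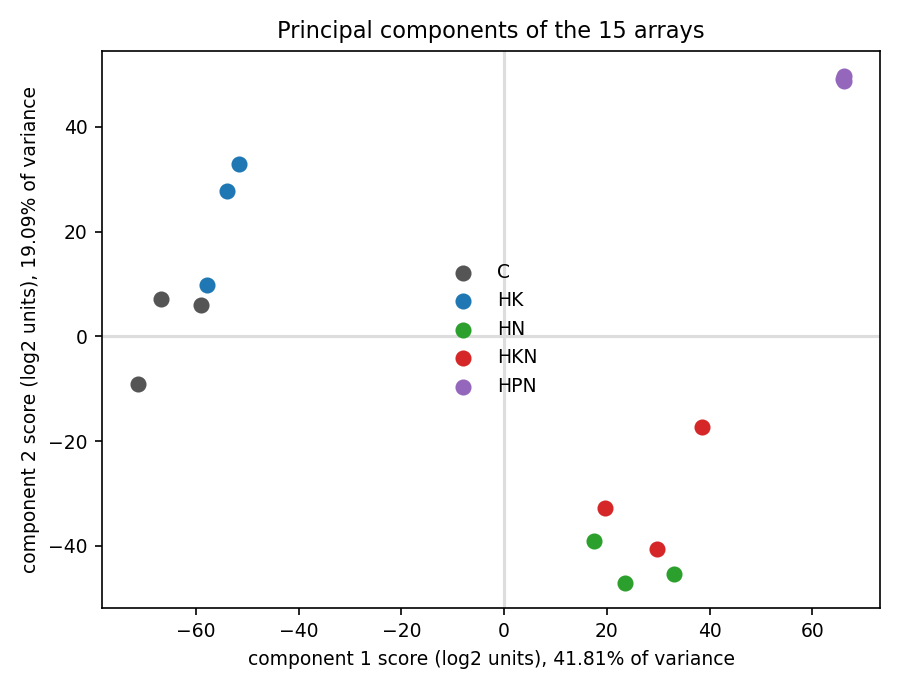
First principal component (41.8% of variance) against the second (19.1%) for the 15 arrays, 1 point per array and 1 colour per group, in units of component score. C and HK lie on the negative side of the first component, and HN, HKN and HPN on its positive side.

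**Figure D2:**
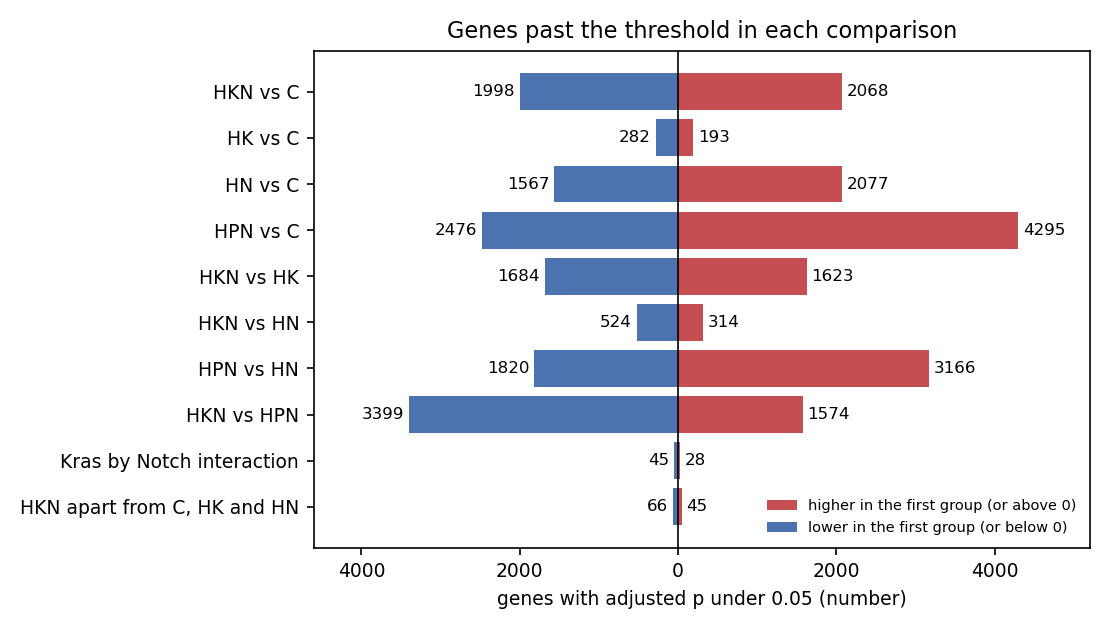
Bars give the number of genes past the adjusted p threshold of 0.05 in each comparison, split into genes higher and genes lower in the first-named group. Counts run from 73 for the interaction to 6771 for HPN against C.

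HK against C asked what active Kras does alone. Serpinb2, an inhibitor of plasminogen activators, rose from 6.95 ± 1.31 in C to 14.06 ± 1.08 in HK (SD, n = 3), a change of 7.11 ± 0.59 (SE; limma, Benjamini-Hochberg adjusted p = 7.14e-05). Cldn6, a tight junction protein, fell from 13.42 ± 0.42 to 5.12 ± 1.57 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00438). Ifitm3, an interferon-induced membrane protein that blocks viral entry, fell by 6.83, and Mmp7, a matrix metalloprotease, fell by 6.38. Apob, the main protein of low-density lipoprotein, rose by 4.31, and Acsm3, an acyl-CoA synthetase, by 4.42. Spink4 rose by 4.23 and Agr2, a disulfide isomerase needed for mucin folding, by 3.96, while the gastric and mucous list did not pass, with 4 of 18 higher (camera, Benjamini-Hochberg adjusted p = 0.0591; adjusted p = 0.476 with an estimated correlation). The other increases named by rule were Far2, Lgals2, Fam3b, Vsig1 and Gsta2, between 4.04 and 5.12. The other decreases were Fscn1 (-6.20), an actin bundler, Ltf (-5.63), Piezo2 (-5.02), Htr1b (-4.72), Tnc (-4.65), Sox17 (-4.48), a biliary transcription factor, and Ifi211 (-4.36). In all, 475 genes passed the threshold, 193 higher and 282 lower (limma, Benjamini-Hochberg over 14627 genes; 2325 at an unadjusted p under 0.05). That number fell to between 196 without HK replicate 5 and 310 without HK replicate 4 and to 255 when the HPN arrays were left out, and it was 1347 with array weights. Without HK replicate 5 the calls on Agr2 (adjusted p = 0.144), Spink4 (0.14), Ltf (0.107), Gsta2 (0.0701) and Lgals2 (0.0693) ended. That on Far2 ended without C replicate 1 (0.0641), and these calls except that on Gsta2 also ended without at least 1 other array.

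Among the gene lists fixed before the data were examined, 10 of 30 differed between HK and C. NF-kB cytokines and chemokines were lower as a list, with 3 of 23 measured members lower (7 adjusted over the list alone) and a median of -0.83 (camera, Benjamini-Hochberg adjusted p = 1.14e-07; adjusted p = 0.302 with an estimated correlation). The 3 were Lif (-1.63), Tnfaip2 (-1.12) and Birc3 (-1.02), an inhibitor of apoptosis. Cell cycle genes had a median of 0.62 (camera, Benjamini-Hochberg adjusted p = 5.62e-07; adjusted p = 0.476 with an estimated correlation), though Tk1 (0.78), a thymidine kinase, alone passed of 28 (1 adjusted over the list alone). NRF2 targets, genes of the antioxidant response, had a median of 0.49 and 3 of 16 higher (4 adjusted over the list alone): Osgin1 (1.60), Gclc (1.54), which starts glutathione synthesis, and Gsta3 (1.52) (camera, Benjamini-Hochberg adjusted p = 0.000517; adjusted p = 0.343 with an estimated correlation). Genes of epithelial-mesenchymal transition had a median of -0.39 (camera, Benjamini-Hochberg adjusted p = 0.00946; adjusted p = 0.343 with an estimated correlation), with Fscn1, Tnc and Fn1 (-2.16) lower and Snai2 (0.98) higher of 13 (5 lower and 1 higher adjusted over the list alone). In the list of matrix proteases, Mmp7, Plat (-1.77) and Timp1 (-1.63) were lower of 14 (5 lower and 1 higher adjusted over the list alone), with a median of -0.13 (camera, Benjamini-Hochberg adjusted p = 0.0325; adjusted p = 0.33 with an estimated correlation). FoxO-activated genes that Akt represses had a median of -0.24 (camera, Benjamini-Hochberg adjusted p = 0.0251; adjusted p = 0.476 with an estimated correlation), with Foxo1 (-1.13) and Sesn3 (-0.86) lower of 15 (3 adjusted over the list alone).

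Other list calls in HK included a median of 0.37 for cholesterol and fatty acid synthesis (camera, Benjamini-Hochberg adjusted p = 0.00234; adjusted p = 0.476 with an estimated correlation), where Fads1 (-1.47), a fatty acid desaturase, was the 1 of 24 past the threshold and was lower (1 lower and 1 higher adjusted over the list alone). Glycolysis and hypoxia genes had a median of 0.51 (camera, Benjamini-Hochberg adjusted p = 0.0101; adjusted p = 0.505 with an estimated correlation) with 0 of 21 past the threshold by limma (5 at an unadjusted p under 0.05, 0 adjusted over the list alone), and Pfkp stood at 1.28 and Ndrg1 at -1.05. The interferon response had a median of -0.56 (camera, Benjamini-Hochberg adjusted p = 0.00946; adjusted p = 0.553 with an estimated correlation) with 0 of 20 past the threshold by limma (2 at an unadjusted p under 0.05, 0 adjusted over the list alone), and Bst2 stood at -3.03 and Oasl2 at -1.97. ERK pathway output, the feedback genes of the Kras-MAPK route, was not called: 1 of 18, the receptor gene Epha4 (-1.05), was lower (3 adjusted over the list alone), and its median of 0.02 and its mean and test differed in sign (camera, Benjamini-Hochberg adjusted p = 0.206). Without C replicate 4 list calls ended for interferon (adjusted p = 0.596), FoxO (0.154), glycolysis (0.0893), and cholesterol, epithelial-mesenchymal transition and matrix proteases (0.0699 each). Calls also ended without HK replicate 4 for glycolysis (0.553), without HK replicate 6 for FoxO (0.0849) and matrix proteases (0.0595, median 0.01), and without C replicate 1 for matrix proteases (0.0538). With median centring the matrix call ended (0.0554), and with the dimmest 50% of probe sets left out so did the matrix (0.0552) and interferon calls (0.0949). Of 35 named genes called in HK, 15 kept the call in every fit without 1 array.

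HN against C asked what active Notch does alone. Keratin 14, the basal keratin of stratified epithelium, rose from 5.49 ± 0.54 in C to 15.13 ± 1.47 in HN (SD, n = 3), a Krt14 change of 9.63 ± 0.69 (SE; limma, Benjamini-Hochberg adjusted p = 1.05e-06). Hp, which encodes the haemoglobin scavenger haptoglobin, rose from 4.74 ± 0.90 to 15.53 ± 2.46 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 5.46e-06). Flt1, a receptor for vascular endothelial growth factor, rose by 8.81, and Dsg3, a desmosomal cadherin of squamous epithelium, by 8.18. Muc1, a mucin of the apical membrane, fell by 9.02 from 17.48 ± 0.23 in C (SD, n = 3), and Ambp, the precursor of a protease inhibitor made by liver, fell by 9.42. The other increases were Depp1 (8.03), Tph1 (7.77), which starts serotonin synthesis, Ccdc141 (7.71), Pir (7.02), U90926 (6.88) and Krt16 (6.70). The other decreases were Anxa13 (-8.10), Ctse (-7.86), a gastric aspartic protease, Ivl (-7.09), an envelope protein of keratinocytes, Efemp1 (-6.81), Gcnt3 (-6.64), Cryab (-5.70), Cldn6 (-5.68) and Ctla2a (-5.62), and the call on Cldn6 ended with only these groups in the fit (adjusted p = 0.052). Past the threshold were 3644 genes, 2077 higher and 1567 lower (limma, Benjamini-Hochberg). The Y-linked level was above 6 in 3 of 3 C arrays and 1 of 3 HN arrays.

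Cell cycle genes and squamous and basal genes were among the lists called higher in HN, and none of these calls held with an estimated correlation. Cell cycle genes were higher as a list, with 15 of 28 higher (18 adjusted over the list alone) and a median of 0.96 (camera, Benjamini-Hochberg adjusted p = 7.15e-06; adjusted p = 0.667 with an estimated correlation), led by Ccna2 (2.64), a cyclin. Glycolysis and hypoxia genes were higher as a list, with 12 of 21 higher and 1 lower (14 and 1 adjusted over the list alone) and a median of 1.34 (camera, Benjamini-Hochberg adjusted p = 4.83e-05; adjusted p = 0.667 with an estimated correlation). Bnip3 (3.66), Pfkp (3.50) and Ankrd37 (2.97) led, while Car9 (-3.06), a carbonic anhydrase, fell. Of 14 Notch targets, 6 were higher and 2 lower (7 and 2 adjusted over the list alone), among them Nrarp, Hes1 (2.96), Dtx1 (1.85) and Lfng (-2.08), which modifies Notch receptors, and the median was 0.77 (camera, Benjamini-Hochberg adjusted p = 0.0191; adjusted p = 0.587 with an estimated correlation). In the squamous and basal list 6 of 14 were higher and 2 lower (6 and 2 adjusted over the list alone), with a median of 0.55 (camera, Benjamini-Hochberg adjusted p = 0.0191; adjusted p = 0.283 with an estimated correlation). Krt14, Dsg3 and Krt16 rose there and Ivl fell, and the list gene Trp63 was too dim to be tested. Cholesterol and fatty acid synthesis had 5 of 24 higher (5 adjusted over the list alone) and a median of 0.30 (camera, Benjamini-Hochberg adjusted p = 0.043; adjusted p = 0.667 with an estimated correlation). The largest changes were in Stard4 (1.84), Scd1 (1.71), Msmo1 (1.27) and Sqle (1.01). The cholesterol call ended with quantile normalization (adjusted p = 0.0916) and without C replicate 4 (0.171), HN replicate 4 (0.119) or HN replicate 2 (0.0633). The Notch and squamous calls ended where the dimmest 50% of probe sets were left out (0.0935 each). Car9 missed the threshold without HN replicate 2 (0.165) or C replicate 1 (0.0918), 3 (0.0971) or 4 (0.0704).

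HKN against C, the central contrast of the design, asked what Kras and Notch do together. Acsm3 rose from 4.66 ± 0.22 in C to 14.40 ± 0.78 in HKN (SD, n = 3), a change of 9.74 ± 0.79 (SE; limma, Benjamini-Hochberg adjusted p = 1.88e-06). Flt1 rose from 5.13 ± 0.12 to 14.68 ± 0.23 and Dsg3 from 4.93 ± 0.08 to 14.29 ± 0.10 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 2.78e-11 for both). Lgr5, an R-spondin receptor that marks epithelial stem cells, rose by 6.76, and Trf, which encodes the iron carrier transferrin, by 7.34. Vcam1, an adhesion molecule for leukocytes, fell from 15.59 ± 0.53 to 8.48 ± 0.86 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 1.68e-07), and Csf2, a cytokine that drives myeloid cells, fell by 7.41. Other increases were Depp1 (8.78), a FoxO-responsive gene, Cyp2s1 (7.62), Ccdc141 (7.58), Krt14 (7.33) and Il5ra (7.26). Other decreases were Cldn6 (-9.48), Ambp (-9.15), Ctse (-7.94), Muc1 (-7.56), Igfbp7 (-7.30), Fscn1 (-7.04), Slco3a1 (-6.93) and Lgals1 (-6.46). In total 4066 genes differed, 2068 higher and 1998 lower (limma, Benjamini-Hochberg). The Y-linked level was above 6 in 3 of 3 C arrays and 1 of 3 HKN arrays.

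The inflammatory and hypoxia lists moved in opposite directions in HKN. NF-kB cytokines and chemokines were lower as a list, with 14 of 23 lower (16 adjusted over the list alone) and a median of -1.88 (camera, Benjamini-Hochberg adjusted p = 1.72e-09; adjusted p = 0.159 with an estimated correlation), led by Csf2, Ccl2 (-6.30), Csf1 (-5.97) and Cxcl2 (-5.76). Glycolysis and hypoxia genes were higher as a list, with 16 of 21 higher (17 adjusted over the list alone) and a median of 1.44 (camera, Benjamini-Hochberg adjusted p = 1.33e-08; adjusted p = 0.303 with an estimated correlation). Largest among them were Bnip3 (4.73), Pfkp (4.70), Ankrd37 (4.25) and Ndrg1 (3.83). Cell cycle genes had 10 of 28 higher (13 adjusted over the list alone) and a median of 0.72 (camera, Benjamini-Hochberg adjusted p = 0.000624; adjusted p = 0.659 with an estimated correlation), led by Cenpa (1.78), the histone of centromeres, and Rrm2 (1.48). NRF2 targets had 10 of 16 higher and 1 lower (11 and 1 adjusted over the list alone) and a median of 1.13 (camera, Benjamini-Hochberg adjusted p = 0.000851; adjusted p = 0.303 with an estimated correlation). Its leading members were Nqo1 (5.04), Slc7a11 (3.07), a cystine transporter, Gsta3 (2.93) and Hmox1 (2.66). Without C replicate 4 the calls on Rrm2 (adjusted p = 0.0856) and Ndrg1 (0.0596) ended, as they did without HKN replicate 3 for Rrm2 (0.0797) and HKN replicate 2 for Ndrg1 (0.0669).

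Mesenchymal, protease and squamous lists also shifted in HKN. Genes of epithelial-mesenchymal transition were lower as a list, with 6 of 13 lower (6 adjusted over the list alone) and a median of -0.47 (camera, Benjamini-Hochberg adjusted p = 0.00256; adjusted p = 0.168 with an estimated correlation): after Fscn1 came Tnc (-5.82), a matrix glycoprotein, Fn1 (-3.87) and Itgb6 (-3.07). Matrix proteases had 7 of 14 lower and 1 higher (8 and 1 adjusted over the list alone) and a median of -0.93 (camera, Benjamini-Hochberg adjusted p = 0.0384; adjusted p = 0.159 with an estimated correlation). Adamts1 (3.97) rose there, while Mmp14 (-2.93), Adam8 (-2.84) and Plau (-2.64) fell. In the squamous and basal list, 6 of 14 were higher and 3 lower (6 and 3 adjusted over the list alone), with a median of 0.35 (camera, Benjamini-Hochberg adjusted p = 0.0343; adjusted p = 0.159 with an estimated correlation), and Krt16 (3.56) and Krt4 (3.51) followed Dsg3 and Krt14. The matrix call ended without C replicate 4 (adjusted p = 0.0505) and without HKN replicate 1 (0.0591).

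Other lists did not pass in HKN as a whole. ERK pathway output had 4 of 18 higher (4 adjusted over the list alone), Dusp4 (1.56), Spred1 (1.48), Spry4 (1.12) and Etv4 (1.10), all feedback genes or factors downstream of MAPK, and a median of 0.11 (camera, Benjamini-Hochberg adjusted p = 0.334). Notch targets had 4 of 14 higher and 3 lower (5 and 3 adjusted over the list alone; adjusted p = 0.26). Biliary epithelium had 4 of 23 higher and 9 lower (4 and 9 adjusted over the list alone; adjusted p = 0.255), with Anxa13 at -5.54, Slc10a2, the ileal-type bile acid transporter of cholangiocytes, at -4.80, Sox17 at -4.34 and Cftr, a chloride channel, at 3.74. Wnt targets and stem cell genes had 4 of 11 higher and 3 lower (adjusted p = 0.67), with Lgr5, Axin2 (3.13) and Ephb3 (2.0) higher and Sox4 (-1.34) lower. Markers of other cell types gave 1 of 13 hepatocyte genes higher and 3 lower, 1 of 8 immune cell genes higher and 2 lower and 1 of 8 motile cilia genes lower, the same counts adjusted over the list alone (adjusted p = 0.67, 0.69 and 0.512). Medians of -0.07 for hepatocyte and 0.12 for immune cell genes had the other sign than their means. Pancreatic and fibroblast lists had 0 of 7 past the threshold each by limma (0 at an unadjusted p under 0.05 and 0 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.748 and 0.983). Autophagy and lysosome genes had 1 of 19 higher and 5 lower (2 and 5 adjusted over the list alone) and p53 targets 1 of 17 higher and 2 lower (1 and 1 adjusted over the list alone; adjusted p = 0.67 for both), and the autophagy median of 0.02 had the other sign than its mean and test.

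**Figure D3:**
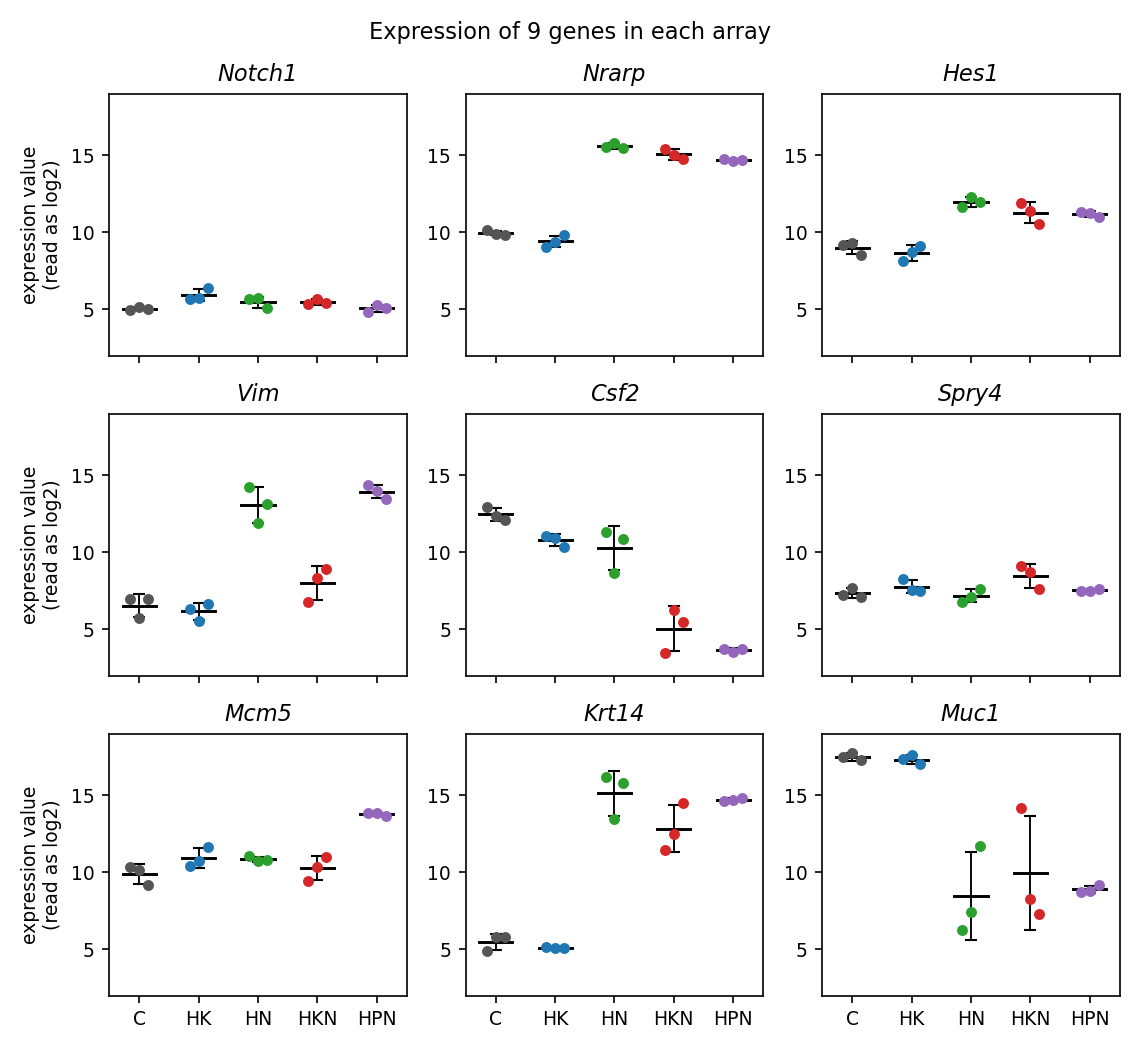
Log2 expression of 9 genes in each group, with 1 point per array, a line at the mean and bars for the SD (n = 3). Nrarp and Hes1 are higher in HN, HKN and HPN than in C and HK, and Csf2 is lower in HKN (5.05) and HPN (3.67) than in C (12.46).

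HPN against C asked what loss of Pten does together with active Notch. Krt14 rose from 5.49 ± 0.54 in C to 14.72 ± 0.10 in HPN (SD, n = 3), a change of 9.23 ± 0.69 (SE; limma, Benjamini-Hochberg adjusted p = 4.75e-07). Vim, the intermediate filament of mesenchymal cells, rose from 6.55 ± 0.73 to 13.94 ± 0.45 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 9.3e-07). Cldn6 fell by 10.60 and Ambp fell by 10.08. Igfbp7, a secreted binder of growth factors, fell from 17.07 ± 0.20 to 9.0 ± 0.22 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 9.24e-09). Inflammatory signals fell as well, with Csf2 at -8.79 and Il1a, an alarm cytokine of epithelium, at -6.96. The other increases were Dsg3 (9.01), Acsm3 (8.61), Hp (8.30), Depp1 (8.18), Flt1 (7.74), Adtrp (7.21), Gp2 (6.85) and Ccdc141 (6.77). Ctse (-9.53), Muc1 (-8.59), Duoxa2 (-7.03), a maturation factor for an oxidase that makes hydrogen peroxide, Fjx1 (-6.78) and Ccdc3 (-6.55) fell too. Of the 6771 genes past the threshold, 4295 were higher and 2476 lower (limma, Benjamini-Hochberg), so 63.4% were higher. That share was 51.9% with quantile normalization (3467 higher and 3211 lower) and 41.8% with arrays centred on their 75th percentile (2866 higher and 3994 lower). The median change of all genes was 0.15 in HPN, against 0.02 with quantile normalization and -0.16 with the 75th percentile, so medians of lists in HPN are given relative to that of all genes. The Y-linked level was above 6 in 3 of 3 C arrays and 1 of 3 HPN arrays.

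Cell cycle and ribosome biogenesis genes were nearly all higher in HPN, and 3 other lists were higher in part. All 28 measured cell cycle genes were higher (28 adjusted over the list alone), with a relative median of 2.2 (camera, Benjamini-Hochberg adjusted p = 3.08e-12; adjusted p = 0.376 with an estimated correlation). Mcm5, part of the replicative helicase, rose from 9.88 ± 0.63 to 13.77 ± 0.11 (SD, n = 3), with Ccna2 (3.75), Birc5 (3.73) and Rrm2 (3.61) next. Ribosome biogenesis had 17 of 18 higher (17 adjusted over the list alone) and a relative median of 1.03 (camera, Benjamini-Hochberg adjusted p = 6.75e-05; adjusted p = 0.411 with an estimated correlation). Members furthest from 0 were Nolc1 (2.09), Rrp12 (1.93), Wdr12 (1.78) and Utp20 (1.59). Cholesterol and fatty acid synthesis had 15 of 24 higher (18 adjusted over the list alone) and a relative median of 0.76 (camera, Benjamini-Hochberg adjusted p = 0.0013; adjusted p = 0.411 with an estimated correlation). First among these were Stard4 (2.16), Pmvk (1.94), Insig1 (1.72) and Acaca (1.58), the enzyme that commits carbon to fatty acids. NRF2 targets had 10 of 16 higher (10 adjusted over the list alone) and a relative median of 1.17 (camera, Benjamini-Hochberg adjusted p = 0.021; adjusted p = 0.411 with an estimated correlation). The biggest shifts were in Nqo1 (4.52), Srxn1 (2.70), Slc7a11 (2.62) and Hmox1 (2.29). The unfolded protein response had 9 of 17 higher (9 adjusted over the list alone) and a relative median of 0.43 (camera, Benjamini-Hochberg adjusted p = 0.021; adjusted p = 0.465 with an estimated correlation). The largest changes were in Creld2 (2.16), Dnajc3 (1.73), Sdf2l1 (1.65) and Dnajb11 (1.57). The last 2 list calls ended where the dimmest 50% of probe sets were left out (adjusted p = 0.0588 and 0.0595).

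NF-kB, FoxO and biliary genes were among the lists lower in HPN. NF-kB cytokines and chemokines had 16 of 23 lower and 2 higher (16 and 2 adjusted over the list alone) and a relative median of -2.79 (camera, Benjamini-Hochberg adjusted p = 1.05e-06; adjusted p = 0.325 with an estimated correlation), with Csf1 (-6.0) and Lif (-4.77) behind Csf2 and Il1a. FoxO-activated genes that Akt represses had 6 of 15 lower and 1 higher (9 and 3 adjusted over the list alone) and a relative median of -0.89 (camera, Benjamini-Hochberg adjusted p = 0.0107; adjusted p = 0.383 with an estimated correlation). Largest among them were Pik3ip1 (-2.35), an inhibitor of PI3K, Fbxo32 (-2.24), Ccng2 (-2.24) and Sesn3 (-2.17). In the list of epithelial-mesenchymal transition 6 of 13 were lower and 3 higher (7 and 3 adjusted over the list alone), with a relative median of -1.07 (camera, Benjamini-Hochberg adjusted p = 0.0195; adjusted p = 0.376 with an estimated correlation). Vim rose there while Fscn1 (-6.22), Tnc (-5.11) and Fn1 (-3.70) fell. YAP targets had 9 of 17 lower and 2 higher (10 and 2 adjusted over the list alone) and a relative median of -1.12 (camera, Benjamini-Hochberg adjusted p = 0.021; adjusted p = 0.383 with an estimated correlation), with Axl (-6.20), a receptor tyrosine kinase, and Ccn1 (-3.13) lower and Il33 (6.0) higher. Matrix proteases had 7 of 14 lower and 2 higher (7 and 2 adjusted over the list alone) and a relative median of -0.86 (camera, Benjamini-Hochberg adjusted p = 0.0289; adjusted p = 0.325 with an estimated correlation), with Adamts1 at 4.31, Adam8 at -4.01, Plau at -3.75 and Mmp14 at -3.53. Biliary epithelium had 9 of 23 lower and 1 higher (9 and 1 adjusted over the list alone) and a relative median of -0.43 (camera, Benjamini-Hochberg adjusted p = 0.0352; adjusted p = 0.383 with an estimated correlation), with Anxa13 (-4.84), Sox17 (-4.79) and Slc10a2 (-3.34) lower and Cftr (2.89) higher. In the endothelial list of 4, Flt1 and Tie1 (1.09) were higher (2 adjusted over the list alone), with a relative median of 0.58 (camera, Benjamini-Hochberg adjusted p = 0.0414; adjusted p = 0.376 with an estimated correlation). The endothelial markers Pecam1, Cdh5, Kdr, Tek, Emcn and Cldn5 were too dim to be tested. The endothelial and biliary calls ended without C replicate 3 (adjusted p = 0.0651 for both) and where the dimmest 50% of probe sets were left out (0.0532 and 0.0604), and the endothelial call also without HPN replicate 2 (0.052) and with no filter on dim probe sets (0.169). Notch targets as a list did not pass, with 6 of 14 higher and 3 lower (camera, Benjamini-Hochberg adjusted p = 0.817).

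**Figure D4:**
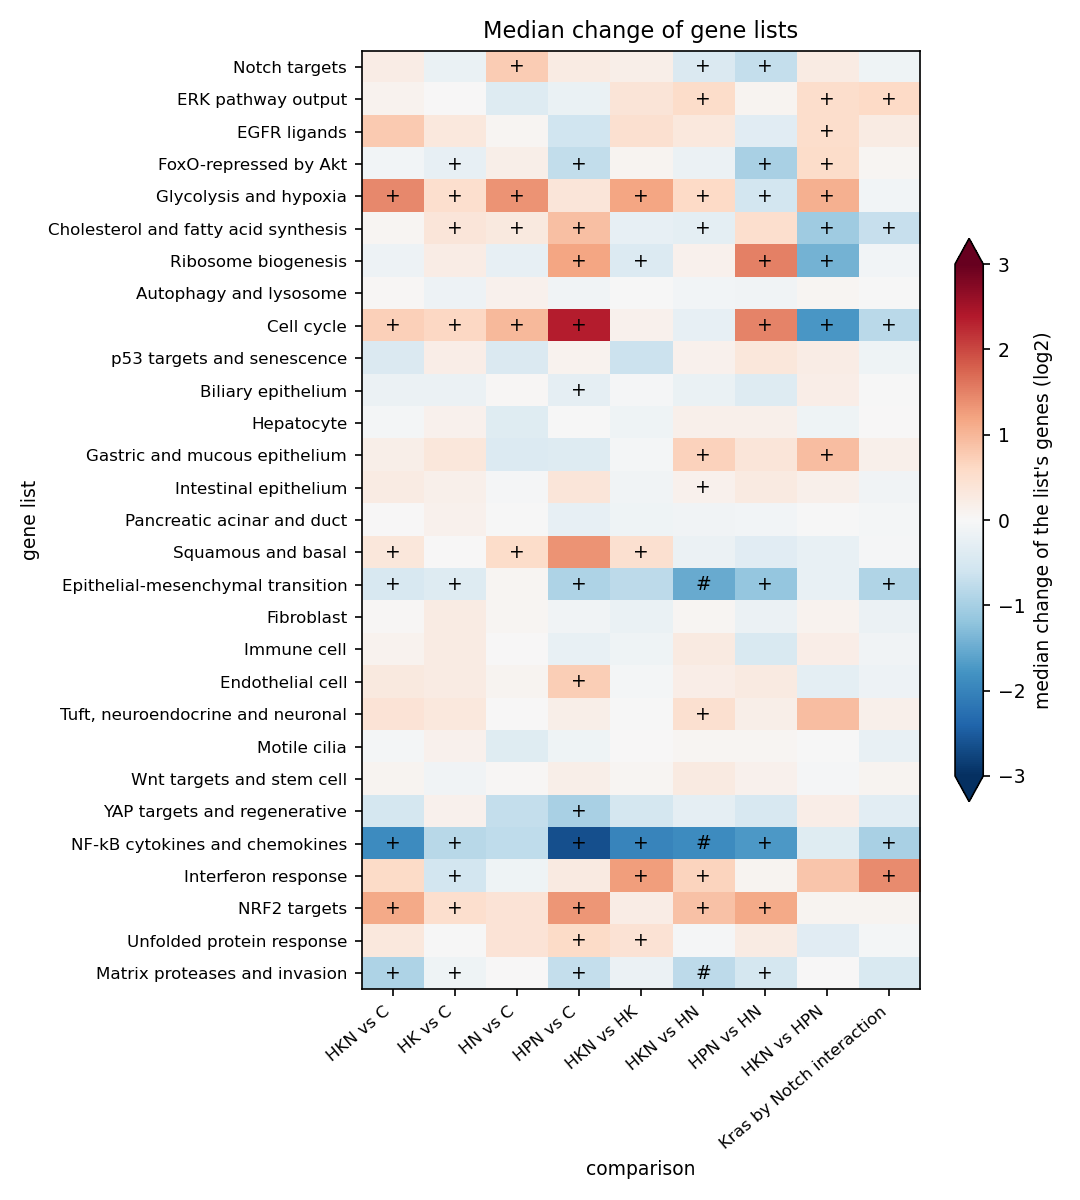
Median log2 change of the gene lists shown (down) in each comparison (across), with red for higher and blue for lower and the scale limited to 3 each way. A plus marks a camera adjusted p under 0.05 and a hash a call kept with an estimated correlation, which 3 of 270 tests reached, all in HKN against HN.

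HKN against HK asked what Notch adds to active Kras. Dsg3 rose from 4.50 ± 0.52 in HK to 14.29 ± 0.10 in HKN (SD, n = 3), a change of 9.79 ± 0.26 (SE; limma, Benjamini-Hochberg adjusted p = 2.7e-11). Flt1 rose by 9.33, Ccdc141 by 9.19 and Trf, from 9.40 ± 0.87 to 17.56 ± 0.42 (SD, n = 3), by 8.16. Apob fell from 13.86 ± 1.16 to 5.62 ± 0.97 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 8.44e-06), and Serpinb2, the strongest increase of Kras alone, fell by 7.84. St8sia6 (8.05), a sialyltransferase, and Depp1 (8.03) rose, and Anxa13 (-7.83), Lgals2 (-7.69), Muc1 (-7.38) and Ctse (-7.18) fell. The threshold was passed by 3307 genes, 1623 higher and 1684 lower (limma, Benjamini-Hochberg), and by 2150 with only these groups in the fit. With arrays centred on their medians, the share higher moved from 49.1% to 60.4% (2082 higher and 1365 lower). The Y-linked level was above 6 in 3 of 3 HK arrays and 1 of 3 HKN arrays, and with it as a covariate 2077 genes passed.

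The hypoxia list was higher and the cytokine list lower when Notch was added to Kras. Glycolysis and hypoxia had 10 of 21 higher (13 adjusted over the list alone) and a median of 1.19 (camera, Benjamini-Hochberg adjusted p = 2.26e-06; adjusted p = 0.483 with an estimated correlation). Its leading members were Ndrg1 (4.88), Bnip3 (3.90), Ankrd37 (3.61) and Pfkp (3.42). NF-kB cytokines and chemokines had 13 of 23 lower and 1 higher (13 and 1 adjusted over the list alone) and a median of -1.98 (camera, Benjamini-Hochberg adjusted p = 0.000172; adjusted p = 0.436 with an estimated correlation). Members furthest from 0 were Csf2 (-5.75), Csf1 (-4.58), Ccl20 (-4.46) and Cxcl5 (-4.33). In the squamous and basal list 4 of 14 were higher and 3 lower (5 and 3 adjusted over the list alone), with a median of 0.49 (camera, Benjamini-Hochberg adjusted p = 0.0326; adjusted p = 0.252 with an estimated correlation), led by Dsg3 and Krt14 (7.71). The interferon response had 3 of 20 higher (3 adjusted over the list alone) and a median of 1.25 (camera, Benjamini-Hochberg adjusted p = 0.00304; adjusted p = 0.635 with an estimated correlation), with Bst2 (3.36), which tethers virus particles, and Ifih1 (2.14), a sensor of viral RNA. Ribosome biogenesis had 3 of 18 lower, led by Utp20 at -1.19 (2 adjusted over the list alone) and a median of -0.41 (camera, Benjamini-Hochberg adjusted p = 0.0365; adjusted p = 0.635 with an estimated correlation). The unfolded protein response had 4 of 17 higher and 1 lower (5 and 1 adjusted over the list alone) and a median of 0.42 (camera, Benjamini-Hochberg adjusted p = 0.0365; adjusted p = 0.596 with an estimated correlation), with Xbp1 (1.27) and Dnajb9 (1.07) first.

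Of these list calls, that on interferon depended on HKN replicate 2, without which its median was 0.12 in place of 1.25 (adjusted p = 0.401). The other calls that ended without 1 array kept their direction, as the squamous call did without HK replicate 5 (median 0.33 in place of 0.49, adjusted p = 0.0558). The unfolded protein call ended with quantile normalization (0.0902) and without HK replicate 4 (0.0593) or 5 (0.0535) or HKN replicate 1 (0.0702) or 3 (0.0717). Ribosome biogenesis lost its call without HK replicate 5 (0.0877) or 6 (0.129) or HKN replicate 1 (0.208) or 2 (0.0816). Where the dimmest 50% of probe sets were left out, the interferon and squamous calls ended (0.0676 each), as did the unfolded protein call (0.0957). Bst2 missed the threshold without HKN replicate 2 (0.124) or HK replicate 5 (0.108) or 6 (0.105).

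HKN against HN asked what Kras adds to active Notch. Gcnt3, a glycosyltransferase that branches mucin glycans, rose from 6.60 ± 1.4 in HN to 14.69 ± 0.86 in HKN (SD, n = 3), a change of 8.09 ± 0.54 (SE; limma, Benjamini-Hochberg adjusted p = 3.46e-06). Reg3g, an antibacterial lectin of gut epithelium, rose by 7.06, Aqp5, a water channel of glands, by 5.65, and Agr2 by 4.92. Igfbp7 fell from 15.52 ± 0.74 to 9.77 ± 0.71 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 3.46e-06), Cdh6, a cadherin of the developing kidney, from 15.50 ± 0.49 to 9.22 ± 1.34, and Tph1 by 6.95. Tnfrsf8 (5.23) and Teddm3 (4.82) rose, and Clca3b (-6.62), Osr1 (-5.65) and Csf2 (-5.22) fell. Past the threshold were 838 genes, 314 higher and 524 lower (limma, Benjamini-Hochberg), against 79 with only these groups in the fit and 509 without the HPN arrays. The full fit pools the spread over all groups, of which HKN and HN had the highest median SD (0.280 and 0.263). The count of 838 may therefore be too high. With only these groups in the fit, Gcnt3, Igfbp7, Cdh6 and Tph1 passed the threshold, while Reg3g, Aqp5, Agr2, Tnfrsf8, Teddm3, Clca3b, Osr1 and Csf2 did not (adjusted p from 0.0574 for Csf2 to 0.127 for Agr2).

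Of all 270 list tests, the 3 calls that held with an estimated correlation were in this comparison. NF-kB cytokines and chemokines were lower as a list, with 15 of 23 lower (19 adjusted over the list alone) and a median of -1.89 (camera, Benjamini-Hochberg adjusted p = 5.94e-15; adjusted p = 0.027 with an estimated correlation): Csf2, the monocyte attractant Ccl2 (-4.78), and the neutrophil attractants Cxcl5 (-4.04) and Cxcl2 (-3.91). Genes of epithelial-mesenchymal transition were lower as a list, with 6 of 13 lower (8 adjusted over the list alone) and a median of -1.50 (camera, Benjamini-Hochberg adjusted p = 1.91e-07; adjusted p = 0.027 with an estimated correlation), as Vim dropped from 13.07 ± 1.18 to 8.0 ± 1.11 (SD, n = 3) beside Fscn1 (-4.11), Fn1 (-4.06) and Tgfb2 (-2.56). Matrix proteases were lower as a list, with 4 of 14 lower (7 lower and 1 higher adjusted over the list alone) and a median of -0.77 (camera, Benjamini-Hochberg adjusted p = 0.000851; adjusted p = 0.027 with an estimated correlation), led by Adam8 (-2.73) and Mmp14 (-2.18). Adam8 alone missed the threshold without HN replicate 2 (adjusted p = 0.0746) or 4 (0.0753) or HKN replicate 1 (0.0728).

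The list calls below had few genes past the threshold, and none of them held with an estimated correlation. NRF2 targets had 3 of 16 higher (7 adjusted over the list alone) and a median of 0.88 (camera, Benjamini-Hochberg adjusted p = 3.79e-07; adjusted p = 0.0823 with an estimated correlation), with Slc7a11 (2.39) and Gsta3 (1.54). ERK pathway output had 3 of 18 higher (7 adjusted over the list alone) and a median of 0.56 (camera, Benjamini-Hochberg adjusted p = 0.00019; adjusted p = 0.0823 with an estimated correlation), led by Spry4 (1.3), a feedback inhibitor of receptor kinases. The gastric and mucous list had 3 of 18 higher (5 higher and 1 lower adjusted over the list alone) and a median of 0.70 (camera, Benjamini-Hochberg adjusted p = 0.000576; adjusted p = 0.185 with an estimated correlation): Agr2, Spink4 (4.23) and Vsig1 (2.86). Glycolysis and hypoxia had Car9 (4.33) higher of 21 (1 adjusted over the list alone) and a median of 0.60 (camera, Benjamini-Hochberg adjusted p = 0.00195; adjusted p = 0.586 with an estimated correlation). In the tuft list of 3, Avil (3.88) was higher (1 adjusted over the list alone), with a median of 0.47 (camera, Benjamini-Hochberg adjusted p = 0.00613; adjusted p = 0.0823 with an estimated correlation), and Reg3g was the 1 of 16 intestinal genes higher (1 adjusted over the list alone), with a median of 0.14 (camera, Benjamini-Hochberg adjusted p = 0.0465; adjusted p = 0.12 with an estimated correlation). Cholesterol and fatty acid synthesis had Fads2 (-0.62) lower of 24 (1 adjusted over the list alone) and a median of -0.30 (camera, Benjamini-Hochberg adjusted p = 0.00867; adjusted p = 0.586 with an estimated correlation). Notch targets had Dtx1 (-1.87) and Hey1 (-1.52) lower and Myc (0.87) higher of 14 (6 lower and 1 higher adjusted over the list alone) and a median of -0.44 (camera, Benjamini-Hochberg adjusted p = 0.0135; adjusted p = 0.164 with an estimated correlation). The interferon response had 0 of 20 past the threshold by limma (3 at an unadjusted p under 0.05, 0 adjusted over the list alone), with Irf7 at 1.31 and Mx1 at 1.28, and a median of 0.67 (camera, Benjamini-Hochberg adjusted p = 0.0119; adjusted p = 0.725 with an estimated correlation).

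Some of these calls also ended without 1 array. Without HKN replicate 2 the interferon median was -0.40 (adjusted p = 0.174) in place of 0.67, and without HN replicate 3 the call ended (0.0606). Notch targets lost their call without HN replicate 3 (0.0606) or HKN replicate 3 (0.135), intestinal genes without HN replicate 2 (0.158) or 3 (0.0606), and glycolysis without HN replicate 2 (0.0505). Intestinal genes also lost it with quantile normalization (0.0961) or no filter on dim probe sets (0.0939), and tuft genes with no such filter (0.432). The tuft list genes Pou2f3, Trpm5 and Il25 were too dim to be tested. Spry4 missed the threshold without HN replicate 2 (0.137) or 3 (0.0878) or HKN replicate 1 (0.143) or 2 (0.129). Spink4 did so without HN replicate 2 (0.0638) or 4 (0.0687) or HKN replicate 1 (0.0685) or 2 (0.0796), and Vsig1 without HN replicate 3 (0.066) or HKN replicate 1 (0.0698) or 2 (0.0708). Of 40 named genes called in this comparison, 26 kept the call in every fit without 1 array.

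HPN against HN asked what loss of Pten adds to active Notch. Adtrp, which hydrolyses fatty acid esters, rose from 5.74 ± 2.08 in HN to 12.01 ± 0.64 in HPN (SD, n = 3), a change of 6.26 ± 0.87 (SE; limma, Benjamini-Hochberg adjusted p = 0.000153). Reg3g rose by 5.76, and Zscan4f, a gene of 2-cell embryos and of a rare state of stem cells in culture, from 6.69 ± 1.59 to 10.97 ± 1.08 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.000761). Csf2 fell by 6.60, Igfbp7 by 6.52 and Tph1 by 6.28, and Lama3, a chain of the basement membrane protein laminin, by 5.65. Tmem54 (4.38), Pramel19 (4.29) and Gp2 (4.25) rose, and Osr1 (-5.79) and Ifitm1 (-5.33) fell. In this comparison 4986 genes passed, 3166 higher and 1820 lower (limma, Benjamini-Hochberg), a share of 63.5% higher. That share was 52% with quantile normalization (2554 higher and 2357 lower) and 43.2% with the 75th percentile (2164 higher and 2842 lower), and the median of all genes moved from 0.12 to 0.00 and -0.11.

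Growth lists were higher in HPN than in HN. Cell cycle genes had 24 of 28 higher (26 adjusted over the list alone) and a relative median of 1.38 (camera, Benjamini-Hochberg adjusted p = 3.19e-09; adjusted p = 0.443 with an estimated correlation). First among these were E2f1 (2.99), Mcm5 (2.92), Cdc20 (2.92) and Aurka (2.47). Ribosome biogenesis had 17 of 18 higher (17 adjusted over the list alone) and a relative median of 1.4 (camera, Benjamini-Hochberg adjusted p = 1.25e-08; adjusted p = 0.342 with an estimated correlation). The biggest shifts were in Nolc1 (2.21), Rrp12 (2.13), Nop16 (2.02) and Wdr12 (2.02). NRF2 targets had 9 of 16 higher and 1 lower (10 and 1 adjusted over the list alone) and a relative median of 1.01 (camera, Benjamini-Hochberg adjusted p = 0.012; adjusted p = 0.443 with an estimated correlation). The largest changes were in Osgin1 (2.76), Srxn1 (2.38), Slc7a11 (1.95) and Cbr3 (1.77). FoxO-activated genes had 7 of 15 lower (8 adjusted over the list alone) and a relative median of -1.10 (camera, Benjamini-Hochberg adjusted p = 0.000781; adjusted p = 0.318 with an estimated correlation). Largest among them were Ccng2 (-2.83), Sesn3 (-1.59), Pik3ip1 (-1.50) and Fbxo32 (-1.36). NF-kB genes had 13 of 23 lower and 1 higher (17 and 2 adjusted over the list alone) and a relative median of -1.83 (camera, Benjamini-Hochberg adjusted p = 6.79e-07; adjusted p = 0.177 with an estimated correlation), with Il1a (-4.95), Csf3 (-4.59) and Csf1 (-3.19) after Csf2.

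Lists lower in HPN than in HN had part of their genes past the threshold, and none of these calls held with an estimated correlation. Glycolysis and hypoxia had 5 of 21 lower (5 adjusted over the list alone) and a relative median of -0.68 (camera, Benjamini-Hochberg adjusted p = 0.0021; adjusted p = 0.595 with an estimated correlation), with Ndrg1 (-4.26) and Bnip3 (-3.92), both induced by low oxygen. Notch targets had 6 of 14 lower and 1 higher (7 and 1 adjusted over the list alone) and a relative median of -0.83 (camera, Benjamini-Hochberg adjusted p = 0.0021; adjusted p = 0.177 with an estimated correlation). Its leading members were Bcl2 (-2.13), Jag1 (-2.05), a Notch ligand, and Dtx1 (-1.52). Epithelial-mesenchymal transition had 7 of 13 lower and 1 higher (8 and 2 adjusted over the list alone) and a relative median of -1.27 (camera, Benjamini-Hochberg adjusted p = 0.0021; adjusted p = 0.207 with an estimated correlation). Members furthest from 0 were Fn1 (-3.89), Fscn1 (-3.29), Cdh2 (-2.80) and Mmp14 (-2.78). Matrix proteases had 4 of 14 lower and 1 higher (4 and 1 adjusted over the list alone) and a relative median of -0.65 (camera, Benjamini-Hochberg adjusted p = 0.0117; adjusted p = 0.177 with an estimated correlation). First among these were Adam8 (-3.89), Plau (-2.94), Mmp14 (-2.78) and Mmp13 (-2.05). The Notch call ended where the dimmest 50% of probe sets were left out (adjusted p = 0.102).

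HKN against HPN set the combined genotypes against each other. Tspan2, a tetraspanin, was at 11.45 ± 0.64 in HKN and 5.61 ± 0.20 in HPN (SD, n = 3), a difference of 5.84 ± 0.62 (SE; limma, Benjamini-Hochberg adjusted p = 4.41e-05). The hypoxia genes Ndrg1 (5.19) and Bnip3 (5.0), which drives removal of mitochondria, were higher in HKN. Vim was at 8.0 ± 1.11 in HKN and 13.94 ± 0.45 in HPN (SD, n = 3), and the small heat shock protein gene Hspb8 was lower by -4.69 in HKN. Kbtbd11 (4.94), Teddm3 (4.67) and Fut2 (4.56), which fucosylates mucosal glycans, were higher, and H1f1 (-3.99), Rps4l (-3.90), Irak3 (-3.87) and Tdpoz7 (-3.78) lower. The threshold was passed by 4973 genes, 1574 higher and 3399 lower in HKN (limma, Benjamini-Hochberg), a share of 31.7% higher. That share was 47.1% with quantile normalization (2259 higher and 2537 lower) and 61.2% with the 75th percentile (3239 higher and 2057 lower), and the median of all genes moved from -0.12 to 0.02 and 0.20.

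Growth lists were lower in HKN than in HPN. Cell cycle genes had 27 of 28 lower (28 adjusted over the list alone) and a relative median of -1.62 (camera, Benjamini-Hochberg adjusted p = 3.22e-11; adjusted p = 0.462 with an estimated correlation). The biggest shifts were in Mcm5 (-3.50), E2f1 (-3.28), Cdc20 (-2.85) and Birc5 (-2.71). Ribosome biogenesis had 17 of 18 lower (17 adjusted over the list alone) and a relative median of -1.31 (camera, Benjamini-Hochberg adjusted p = 9.45e-08; adjusted p = 0.462 with an estimated correlation). The largest changes were in Rrp12 (-2.70), Utp20 (-2.47), Nolc1 (-2.05) and Nop16 (-1.95). Cholesterol and fatty acid synthesis had 14 of 24 lower (14 adjusted over the list alone) and a relative median of -0.95 (camera, Benjamini-Hochberg adjusted p = 0.00262; adjusted p = 0.562 with an estimated correlation). Largest among them were Fasn (-2.50), fatty acid synthase, Mvk (-1.89), Acaca (-1.75) and Fads1 (-1.57). Glycolysis and hypoxia had 10 of 21 higher (11 adjusted over the list alone) and a relative median of 1.20 (camera, Benjamini-Hochberg adjusted p = 3.52e-07; adjusted p = 0.462 with an estimated correlation), with Ankrd37 (3.01) and Egln3 (2.95) after Ndrg1 and Bnip3. ERK pathway output had 7 of 18 higher (7 adjusted over the list alone) and a relative median of 0.64 (camera, Benjamini-Hochberg adjusted p = 0.00803; adjusted p = 0.462 with an estimated correlation). Its leading members were Ier3 (2.15), Spred3 (1.77), Phlda1 (1.46) and Dusp6 (0.97), a phosphatase that switches ERK off. FoxO-activated genes had 4 of 15 higher (4 adjusted over the list alone) and a relative median of 0.66 (camera, Benjamini-Hochberg adjusted p = 0.0118; adjusted p = 0.489 with an estimated correlation), led by Ccng2 (3.0). The gastric and mucous list had Spink4 (3.22), Vsig1 (1.91) and Gata4 (1.24) higher of 18 (1 adjusted over the list alone) and a relative median of 1.04 (camera, Benjamini-Hochberg adjusted p = 0.00292; adjusted p = 0.462 with an estimated correlation). Of 6 EGFR ligands, Hbegf (2.93) and Btc (1.56) were higher (2 adjusted over the list alone), with a relative median of 0.65 (camera, Benjamini-Hochberg adjusted p = 0.0241; adjusted p = 0.462 with an estimated correlation), and that call ended with no filter on dim probe sets (adjusted p = 0.11). Vsig1 missed the threshold in 5 of the 6 fits without 1 array (adjusted p up to 0.162, without HKN replicate 1). Spink4 did so without HKN replicate 1 (0.0983) or 2 (0.0746) or HPN replicate 1 (0.0586) or 2 (0.0633).

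The interaction of Kras and Notch asked whether the change that Kras makes differs with Notch active. Mmp7 fell by 6.38 with Kras alone and stood 0.24 higher in HKN than in HN, an interaction of 6.62 ± 1.05 (SE; limma, Benjamini-Hochberg adjusted p = 0.0159). Ifitm3 (5.73), Sting1 (4.80), an adaptor in the response to cytosolic DNA, and Naip5 (4.14), a sensor of bacterial flagellin, also had positive interactions. So did Gcnt3 (5.40) and Htr1b (4.26). Cdh6 had an interaction of -6.14 ± 0.69 (SE; limma, Benjamini-Hochberg adjusted p = 0.00151), with levels of 14.57 ± 0.18 in C, 14.44 ± 0.14 in HK, 15.50 ± 0.49 in HN and 9.22 ± 1.34 in HKN (SD, n = 3). Tph1 (-7.65), Lgals2 (-6.52), Osr1 (-6.04), Serpinb2 (-6.01) and Lrrc32 (-5.51), which holds latent TGF-beta on the cell surface, were the other negative interactions. Tph1 stood at 3.93 in C, 4.64 in HK, 11.70 in HN and 4.76 in HKN, and Osr1 at 3.35, 3.74, 9.06 and 3.41. Both lay under the dim limit of 4.14 in C, so a fall with Kras alone could not show. Their interactions therefore do not decide whether the effect of Kras differs with Notch. Passing here were 73 genes, 28 positive and 45 negative (limma, Benjamini-Hochberg; 1556 at an unadjusted p under 0.05). That number was 261 with array weights, 47 where the dimmest 50% of probe sets were left out and 22 with only the groups compared, and lay between 24 without C replicate 3 and 181 without HN replicate 3. Without HK replicate 5 the calls on Htr1b (adjusted p = 0.118), Lgals2 (0.113), Naip5 (0.0741) and Osr1 (0.0583) ended, as did Mmp7 without C replicate 3 (0.05015) and Lrrc32 without HK replicate 6 (0.0589) or C replicate 1 (0.0511) or 3 (0.0527). Htr1b, Lgals2, Naip5 and Osr1 each missed the threshold without at least 5 of the 12 arrays.

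Lists with a positive interaction included ERK pathway output (median 0.59) and the interferon response (1.41) (camera, Benjamini-Hochberg adjusted p = 1.32e-06 and 2.44e-06; adjusted p = 0.123 and 0.539 with an estimated correlation). Cell cycle (-0.80), cholesterol and fatty acid synthesis (-0.68) and NF-kB genes (-0.98) had negative ones (camera, Benjamini-Hochberg adjusted p = 5.3e-08, 8.88e-07 and 0.00108; adjusted p = 0.539, 0.52 and 0.52 with an estimated correlation). In these 5 lists 0 members passed the threshold by limma, with 6, 3, 11, 11 and 10 at an unadjusted p under 0.05. Adjusted over the list alone, 1 cell cycle, 5 cholesterol and 6 NF-kB genes passed. Epithelial-mesenchymal transition had a median of -0.89 (camera, Benjamini-Hochberg adjusted p = 0.0095; adjusted p = 0.52 with an estimated correlation), with Vim (-4.68) lower of 13 (6 lower and 2 higher adjusted over the list alone). That list call ended without C replicate 3 (adjusted p = 0.0938) or HN replicate 3 (0.0579), and the interferon call without HKN replicate 2 (0.105). The call on Vim ended without 7 of 12 arrays, with the highest adjusted p of 0.0728 without HK replicate 6. Of the 30 lists, camera with an estimated correlation and fry each called 0 for the interaction.

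The last test asked which genes set HKN apart from C, HK and HN alike, and the smallest of the differences is given for each gene. Igfbp7 was at 9.77 ± 0.71 in HKN and between 15.52 and 17.07 in the 3 control groups (SD, n = 3), with a smallest difference of -5.75 (limma, Benjamini-Hochberg adjusted p = 3.56e-06). Vcam1 (-4.51; limma, Benjamini-Hochberg adjusted p = 0.000284), Csf2 (-5.22), Cdh6 (-5.21), Slco3a1 (-4.69), a transporter of prostaglandins, and Tm4sf4 (-4.15) were also lower. Reg3g (6.20), Teddm3 (4.82), Acsm3 (4.68), Synpr (4.26), a synaptic vesicle protein, Kbtbd11 (4.14) and Tnfrsf8 (4.07), which encodes the receptor CD30, were higher. HPN, outside this test, lay on the same side of the controls as HKN for Igfbp7 (9.0), Csf2 (3.67), Reg3g (9.27) and Acsm3 (13.28). Teddm3 (4.96), Kbtbd11 (4.31), Synpr (5.53) and Tnfrsf8 (5.58) were far lower in HPN than in HKN. Levels of Cdh6, Slco3a1, Vcam1 and Tm4sf4 in HPN lay between HKN and the controls. In this test 111 genes passed, 45 higher and 66 lower (limma, largest of the 3 p-values, Benjamini-Hochberg; 926 at an unadjusted p under 0.05). Their number was 170 with array weights, 47 with only the groups compared, 47 without the HPN arrays and 65 with the Y-linked level as a covariate. It was 55 without HKN replicate 2, 64 without HK replicate 5 and 71 without HK replicate 6. Without HKN replicate 2, Kbtbd11 (adjusted p = 0.132) and Tnfrsf8 (0.105) missed the threshold, as did Reg3g without C replicate 4 (0.101). Kbtbd11 missed it in 10 and Reg3g in 9 of the 12 fits without 1 array.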

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

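Tests of scale and of separate handling of the HPN arrays were chosen after the result was seen. The 2 tests that deal residuals again were too, though their criterion was set before their own outcome. Tests on sex and on low spread also had their criterion set before their own outcome. They were written with the Y-linked levels or the HPN count already known, however. The tests with other groupings or splits of the arrays were set before.

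The interaction of Kras and Notch stood out because the change with Kras differed by Notch status in a direct test that 73 genes passed. Its largest values were Mmp7 6.62, Ifitm3 5.73, Gcnt3 5.40, Sting1 4.80, Htr1b 4.26 and Naip5 4.14, and Tph1 -7.65, Lgals2 -6.52, Cdh6 -6.14, Osr1 -6.04, Serpinb2 -6.01 and Lrrc32 -5.51. For Tph1 and Osr1 the C level was under the dim limit, where a fall with Kras alone could not show. Of 100 groupings of the 12 arrays 5, the real one included, gave at least 73 genes, and the highest other gave 641. This decides nothing about chance, because all 4 of the others were among the 7 groupings that set the arrays with active Notch most fully against those without it, and none of the other 92 gave more than 12. With the separate effects of Kras and Notch set aside, the residuals were dealt again among the 12 arrays. Of 100 deals 2, the real one included, gave at least 73 genes, and the highest other gave 146. Any interaction stays in these residuals and raises the spread within groups when dealt. These deals therefore do not decide about chance for the count. Among 1954 probe sets without a gene symbol, which the comparisons did not use, 317 passed the threshold in HKN against C.

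For the genes that set HKN apart from C, HK and HN, 1 of 100 groupings, the real one, gave as many as 111, and the highest other gave 12. This decides nothing about chance either, because each of the other groupings mixed arrays with and without active Notch in at least 2 of the 4 groups, which raises the spread within groups. A further test set HKN and HN, the control group with the fewest genes past the threshold against HKN, to 1 mean. With the residuals dealt again among the 12 arrays, 1 of 100, the real one, gave as many and the highest other gave 2. Differences between HKN and HN stay in these residuals and raise the spread within groups when dealt, which lowers the other counts. This test therefore does not decide about chance for the count. The 6 arrays of a pairwise comparison make 10 splits, too few for a share under 0.05, and in each comparison the real split alone, 1 of the 10, reached its count. Real count and highest other were 4066 and 0 for HKN against C, 475 and 1 for HK against C, 3644 and 1 for HN against C, and 6771 and 0 for HPN against C. They were 3307 and 3 for HKN against HK, 838 and 8 for HKN against HN, 4986 and 0 for HPN against HN, and 4973 and 0 for HKN against HPN.

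Sex is a candidate explanation for counts between groups with and without active Notch, since the Y-linked level was above 6 in 6 of 6 C and HK arrays and 3 of 9 others. If sex were the cause, the array of each Notch group with a high Y-linked level would not share the change from C. Its change was instead 0.866 of that of the other arrays of its group in HKN and 0.814 in HN (median over 3630 and 3255 genes called without it). The HN value argues against sex for the count of HN against C. For HKN the ratio is weaker evidence, because the Y-linked level of HKN replicate 3 was 9.78, also below the C arrays. Its Uty lay 1.91 below the C mean, while Eif2s3y was at that mean. In HPN the ratio was 0.986 over 5698 genes, but the Y-linked level of HPN replicate 2 was 8.77, against 10.54 to 10.76 in the C arrays. With this intermediate level the ratio does not decide about sex for HPN. A smaller part of each difference stays open.

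HPN had the most genes past the threshold of the groups set against C, and more of them higher than lower. Scale alone is argued against for the count, which was 6678 after quantile normalization. Low spread among the HPN arrays could not by itself put this count above the others. The reason is that 1 fit gives a gene the same SE in each comparison with C. Without a test, 3827 genes had a log2 difference from C of 1 or more after that normalization, compared with 2453 in HKN and 2127 in HN. The share of calls that are higher, 51.9% after quantile normalization, cannot be told apart from scale, because that method sets all arrays to 1 distribution. Separate handling of the HPN arrays cannot be told apart from genotype either: their median SD was 0.164, against 0.242 in the next lowest group, and the labels give no dates. A greater response to loss of Pten with active Notch may be present and was not tested apart from these.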

How the results depend on the processing

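Alternatives added after the data were seen were the Y-linked covariate, the fit without HPN arrays and the 75th percentile. Of 178 alternative counts of genes past the threshold, 143 lay within 1.5 times the reported count, and 5 of 10 comparisons did so throughout. Of 378 results on named genes, 295 kept their direction and call in each alternative run, with 360 of 5693 values losing the call and 0 reversed. Of 82 list calls, 3 did so. The cause of these shifts was not tested. Dim signal limits what the arrays can show, and 3 arrays per group limit the counts.

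With only the groups compared, counts were 2150 for HKN against HK (3307 reported), 79 for HKN against HN (838), 22 for the interaction (73) and 47 for HKN apart from its controls (111). This leaves fewer arrays to estimate the spread, which the full fit pools over all groups. Spread also differed by group, with a median SD of 0.164 in HPN, 0.263 in HN and 0.280 in HKN. Pooling can thus give the noisier groups too small an SE and too many calls. Fewer arrays and unequal spread cannot be told apart here. Without the HPN arrays, which had the lowest spread, counts were 255 for HK against C (475), 509 for HKN against HN, 22 for the interaction and 47 for HKN apart. With array weights they were 1347 for HK against C, 261 for the interaction and 170 for HKN apart. With the Y-linked covariate they were 2077 for HKN against HK and 65 for HKN apart. With the dimmest 50% left out, and so fewer genes tested, the interaction had 47. Leaving out 1 array gave 196 to 310 for HK against C, 24 to 181 for the interaction, 55 to 122 for HKN apart, and 76 to 92 called lists. With an estimated correlation 3 of 82 list calls remained, and with fry 59 did. The interferon list in HKN against HN (0.67) had a median of -0.40 (adjusted p = 0.174) without HKN replicate 2 and up to 1.28 without HKN replicate 3, so that HKN array carried its direction.

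Notch1 in HK against C (0.89, limma with Benjamini-Hochberg, adjusted p = 0.0475) lost its call with quantile normalization (0.80, adjusted p = 0.0684), median centring (0.83, 0.0628), no filter (0.89, 0.0535), trend and robust options (0.89, 0.0512) and only the groups compared (0.89, 0.0931). Leaving out 1 array gave 0.66 to 1.02 and no call. In HKN against C, Notch1 passed with array weights (0.55, adjusted p = 0.0487) only.

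The labels do not say what a shared replicate number means, and no shared effect of it was seen. After group means were removed, 15 pairs with a shared number had a median correlation of 0.0007 (-0.15 to 0.21, 1 over 0.1), and 75 other pairs -0.0022. A weak pairing stays open. With a replicate block, HKN against HN had 319 genes past the threshold, 295 of them among the 838.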

Other observations

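The list of 2-cell-stage genes and its tests were chosen after the values were seen, though the test on array background had its criterion set before its result.

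Genes of the 2-cell embryo, such as the Zscan4, Usp17l, Tdpoz and Tcstv families, were higher in HPN. Of 23 listed, 22 were tested, and 22 of 22 were higher in HPN than in C with a median of 3.46 (limma, Benjamini-Hochberg threshold of 0.05) and 22 higher than in HN with a median of 3.15. Zscan4f stood at 4.75 ± 0.11 in C and 10.97 ± 1.08 in HPN (SD, n = 3). Against C, 7 were higher in HKN, 5 in HK and 1 in HN.

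A partial 2-cell-like state in HPN cultures is 1 candidate explanation, set against scale, shared probes and background. Under quantile normalization all 22 kept the call against C and 21 that against HN, and other genes within the same range of C levels had a median change of 0.0809, which argue against scale and raised background. The 4 genes without close paralogs (Zfp352, Spz1, Tmem92 and Arg2) were higher too. They were listed after the values were seen, so this does not decide about shared probes. For the 18 members of families, all higher, single genes and shared probes cannot be told apart, since probe sequences were not used here. No biological explanation beyond genotype was tested.

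The Y-linked genes of HPN replicate 2 lay below the C mean by similar amounts: Kdm5d -1.90, Eif2s3y -1.82 and Uty -1.82. In HKN replicate 3 the same differences were -0.61, 0.01 and -1.91, and in HN replicate 3 -0.28, 0.25 and 0.03.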
